A study of Rattus norvegicus with 17 samples.

How the data were processed

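RNA of neonatal rat ventricular myocyte cultures, given as 5 days old in the labels, was labelled with biotin and read on Affymetrix arrays, 1 per sample. The labels call the samples of a group biological replicates without saying whether separate cultures or plasma donors are meant. The p-values therefore measure the spread between these samples, pooled over the groups of a fit. The plasma share of 10% is stated for the uremic plasma, and neither that of the control plasma nor the medium of the phenylephrine cultures is stated in the labels. The titles of 2 before NHD samples carry 2 replicate numbers, and the last was used. No batch, culture or scan label was given, and whether same-numbered samples share a patient or a culture is not stated.

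The deposited values are log2 expression values made by the authors with RMA, per the submitters' processing notes. RMA subtracts background, makes the arrays' distributions alike by quantile normalization and summarises the probes of each probe set, so that a change shared by most genes would be removed and differences near the floor and the ceiling are compressed. Its version and the probe set definition are not given in the sources used here. The log2 scale was taken from the values, which run from 1.28 to 14.29 with no missing entry. All 17 columns matched a sample. No probe set carried the name of an Affymetrix control, so that 0 were left out and control probe sets that cannot be recognised by name may be among the 29214 tested.

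Probe sets were named with the platform annotation that accompanies the table. Of them, 15310 had 1 gene symbol, 323 several and 13581 none here. Symbols were updated through the Entrez number with an NCBI RefSeq gene table (assembly GRCr8), which held 15279 of them. No coordinates were used, since no genome build belongs to the values. For gene-level work the probe set with the highest mean over all arrays stood for its gene, which left 14506 genes.

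Each probe set was tested with limma 3.58.1 (R 4.3.3), lmFit and eBayes, in 1 fit of all 17 arrays with the 4 groups and no further term (13 residual and 3.32 prior degrees of freedom). Two-sided p-values were adjusted by the Benjamini-Hochberg method over 29214 probe sets, with a threshold of 0.05. Fold changes are differences of group means on the log2 scale, with the standard error of the fit. This error pools the spread of the 4 groups, which was unequal. Root mean square SDs were 0.377 before NHD, 0.245 after NHD, 0.212 with control plasma and 0.179 with phenylephrine. Comparisons with before NHD plasma therefore borrow from tighter groups, and those with phenylephrine rest largely on the spread of the other groups. Gene lists, 27 in number, covered myocyte function, stress, metabolism, signalling and the other cell types such a culture can hold. They were tested at gene level with camera (preset correlation 0.01), and again with an estimated correlation and with fry. Camera asks whether a list moves more than other genes. Fry asks whether a list's genes move one way and compares it with nothing else. The groups, comparisons, lists and alternatives were fixed before the data were examined.

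Named genes followed a rule fixed at the same time. In each comparison these were the 10 largest increases and the 10 largest decreases past the threshold, with the smallest unadjusted p filling up to 5 where fewer passed, up to 4 members of each list by smallest p, and Nppa, Nppb, Acta1, Myh7, Myh6 and Atp2a2 always. Provisional symbols and probe sets with several symbols were left out. Several named genes have a further probe set. The other probe sets of Mt1, Mt2A, Rrm2, Ccnb2, Bax, Pmm1 and Dlat moved in the same direction as the one used, and the dimmer probe set of Cs had a log2 difference of 0.18 between before NHD and control plasma, which did not pass.

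The procedure was tested on simulated data of the same layout. For after against before NHD, 88% of 50 probe sets changed by 1 log2 unit were recovered and 38% of 50 changed by 0.5. For phenylephrine against control plasma these shares were 64% and 14%. The simulation gave all groups the same SD per probe set and drew probe sets independently. In the data the before NHD arrays were more scattered and probe sets varied together, so that recovery there may differ from these shares. Alternatives were the brighter part of the probe sets (mean at or above the median probe set), 1 probe set per gene, a second quantile normalization, a trended robust prior, fits of only the compared groups, array weights, the replicate number as a block, a 1.5-fold minimum, and each array left out in turn. Further settings, chosen after the data were seen, left out the before and after samples numbered 4 or added each array's SD as a term. Values of single samples were also checked for one lying far from the others by Dixon's test.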

Results

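Nocturnal hemodialysis (NHD) is dialysis given overnight for long hours, and uremic plasma is the plasma of people with kidney failure. Cultures of ventricular myocytes from newborn Sprague-Dawley rats received 10% uremic plasma taken before or after NHD, control plasma, or phenylephrine, an alpha-adrenergic agonist that makes cultured myocytes grow. RNA of each sample was read on 1 Affymetrix array, which gave 17 arrays: 6 with plasma from before NHD, 6 with plasma from after NHD, 3 with control plasma and 2 with phenylephrine. The table held log2 RMA values of 29214 probe sets, from 1.28 to 14.29, with array medians between 6.89 and 7.03. The number of arrays limits the precision of every value below, most of all in the phenylephrine group.

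The before NHD arrays were the most scattered. The median probe set had an SD of 0.249 log2 units among them, against 0.160 after NHD, 0.139 with control plasma and 0.0941 with phenylephrine. The first principal component held 45.7% of the variance. Control arrays lay at -72.24 to -50.31 on it and after NHD arrays at 15.15 to 37.20, with phenylephrine at 33.64 and 35.66. Before NHD arrays spanned nearly the whole axis, from -66.50 for replicate 5, among the controls, to 40.85 for replicate 6, beyond the after NHD arrays. The nearest pair of all arrays was before replicate 4 and after replicate 4, whose difference had an SD of 0.205 over probe sets (Pearson r across probe sets = 0.996). The SD of log2 values within an array was lowest in control replicates 1 and 3 (2.245 and 2.252) and in before replicates 1 and 5 (2.244 and 2.269), and 2.29 or more on the other arrays.

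**Figure D1:**
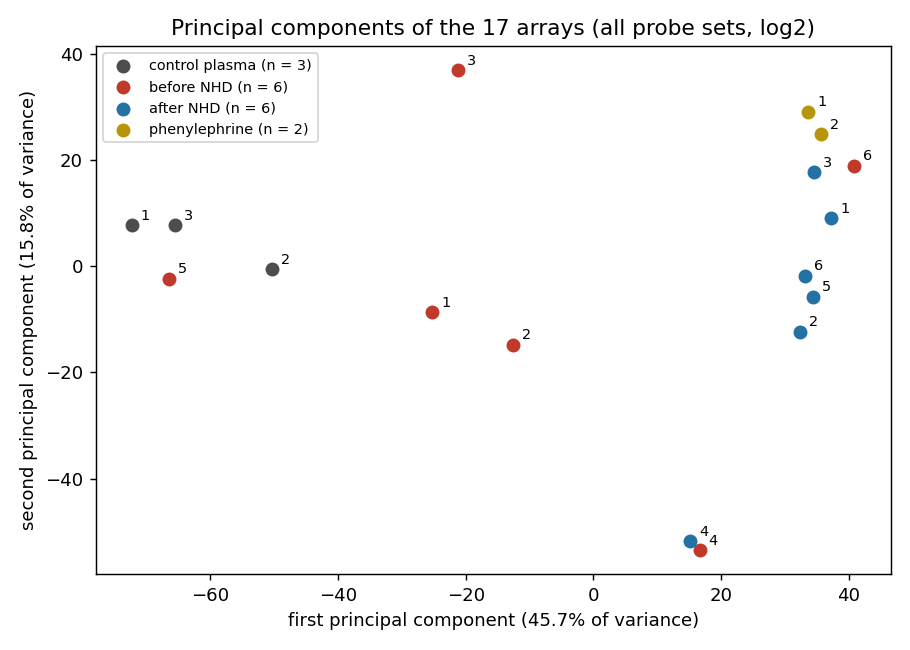
The 17 arrays on the first (45.7% of variance) and second (15.8%) principal components of all probe sets, coloured by group and numbered by replicate. Control arrays lie at the left and after NHD and phenylephrine arrays at the right. The 6 before NHD arrays are spread along nearly the whole first axis, from among the controls to beyond the after NHD arrays.

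Plasma from after NHD was first set against plasma from before NHD, the comparison the series is named for. The largest increases with after NHD plasma were in genes of cell division. Top2a, the topoisomerase that untangles replicated chromosomes, rose by 2.88 ± 0.49 log2 units (SE; adjusted p = 0.0289), with after NHD arrays at 9.77 to 10.57 and before NHD arrays at 5.98 to 9.88. Kif20a, a motor protein of cytokinesis, rose by 2.75 ± 0.43, cyclin A2 (Ccna2) by 2.57 ± 0.45 and cyclin B2 (Ccnb2) by 2.31 ± 0.33. Ect2, Pbk, Plk1, Rrm2, Ccnb1 and Nusap1, which act in DNA synthesis or mitosis, completed the 10 largest increases, at 2.30 to 1.91 log2 units. Of the 42 measured genes of the cell cycle list, 16 rose and 0 fell, with a list median of 0.88. Adjusted over the list alone, 32 rose and 2 fell. The list was called by camera (adjusted p = 2.7e-27) but not with an estimated correlation (adjusted p = 0.26). Its mean was 1.05 log2 units higher after NHD (exact two-sided permutation p = 0.0043, n = 6 and 6; adjusted p = 0.12 over 27 lists). A fibroblast marker, S100a4, rose as well (1.03 ± 0.20), as 1 of the 21 measured genes of the fibroblast list, whose median was 0.37 (camera adjusted p = 0.011; adjusted p = 0.92 with an estimated correlation). The fibroblast call was also lost with the SD of each array as a term (0.098), without before replicates 2, 4 and 5 (0.096, 0.12 and 0.095) and without after replicates 3 and 6 (0.10 and 0.057).

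The largest decreases after NHD were in RT1-CE5, a class I histocompatibility gene (-1.87 ± 0.36), whose probes may also read its near-identical relatives, and in Lxn, a carboxypeptidase inhibitor (-1.24 ± 0.25). Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, fell by 1.04 ± 0.18 log2 units (adjusted p = 0.0289), from 12.67 ± 0.50 (SD, n = 6) before to 11.63 ± 0.20 (SD, n = 6) after NHD. Jam3, Pmm1, Hapln3, the cytokine Lif, Plcl1, Gle1 and Tbcel fell by between 1.08 and 0.65. Cdkn1a was the 1 gene of the 32 in the apoptosis and p53 list to pass over all probe sets, and 10 members fell when adjusted over the list alone. For this list camera gave adjusted p = 0.017, and adjusted p = 0.71 with an estimated correlation. Fads2, a fatty acid desaturase, rose by 0.70 ± 0.14 in the list of liver X receptor and lipogenesis genes. Lists of mitochondrial respiration, glycolysis and contractile genes were called upward by camera and those of oxidative stress and ER stress genes downward, although 0 members passed singly (adjusted p = 0.82 with an estimated correlation for each of these lists). The contractile call was also lost on the brighter probe sets (adjusted p = 0.099), with the SD of each array as a term (0.066), without after replicates 1, 2 and 5 (0.090, 0.12 and 0.055) and without before replicates 3, 4 and 5 (0.11, 0.12 and 0.13). Those of oxidative stress and ER stress genes were lost without before replicate 3 (0.082 and 0.091), as was that of apoptosis and p53 (0.051), and the oxidative stress call without after replicate 4 (0.11). The markers of myocyte hypertrophy did not pass: log2 differences were 0.07 ± 0.06 for Nppa, 0.29 ± 0.19 for Nppb, -0.42 ± 0.19 for Acta1 and 0.08 ± 0.08 for Myh7. Nppa lay between 13.66 and 13.93 on every array, near the top of the scale, where a difference would be compressed. Camera did not call the hypertrophy list (adjusted p = 0.15), nor cholesterol genes (0.10). Both were called upward without the samples numbered 4 (0.034 and 0.033) and with the replicate number as a block (0.0498 and 0.043). Heat shock genes (0.12) were called upward without the samples numbered 4 (0.047). Interferon genes (0.23) were called downward with the SD of each array as a term (0.016).

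In all, 116 probe sets passed (84 higher, 32 lower), and 5402 had an unadjusted p under 0.05, against a mean of 1460.7 expected by chance. Probe sets vary together across arrays, so that such a count can lie far from this mean by chance. The excess alone does not show an effect. With limma, leaving out any of before replicates 1 to 3 or after replicates 1, 2, 3, 5 and 6 left 0 called (4293 to 4916 at an unadjusted p under 0.05), and so did a fit of the 12 arrays alone (4614). Leaving out before replicate 4 gave 2648 (1154 higher, 1494 lower), before replicate 6 gave 2690 (1197 and 1493) and after replicate 4 gave 641 (293 and 348), so that the balance of higher and lower turned, while any other array left out gave 33 to 44.

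**Figure D2:**
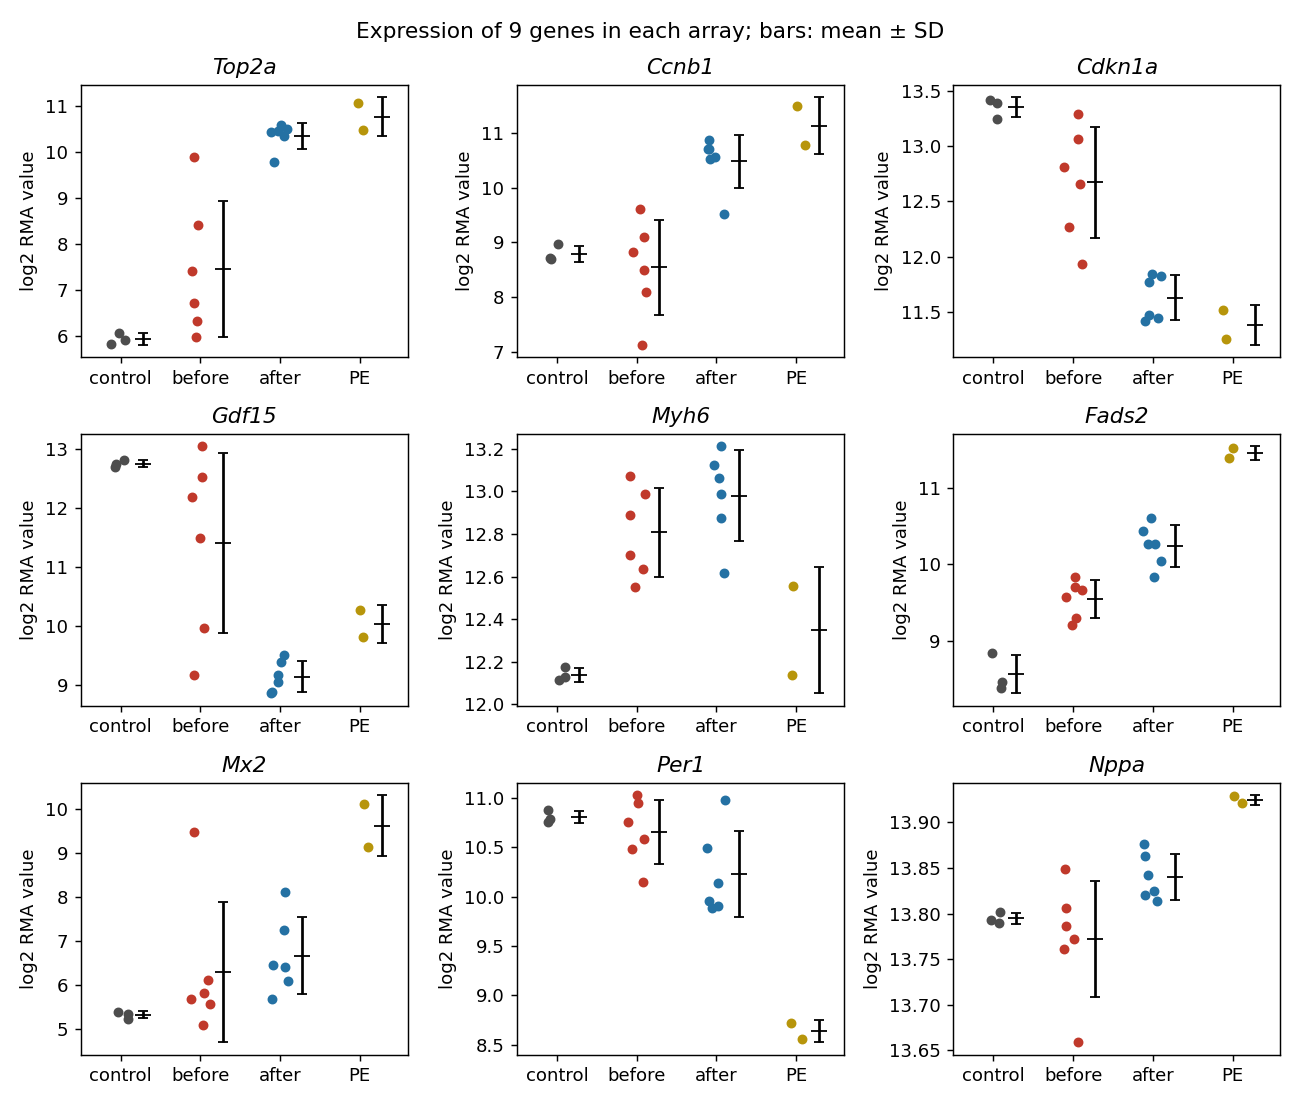
Log2 RMA values of 9 genes on each array, by group (control plasma, before NHD, after NHD and phenylephrine, PE), with group mean and SD as a bar beside the points. Top2a lies at 9.77 or above in all 6 after NHD arrays and at 6.08 or below in the 3 control arrays, while Nppa spans 13.66 to 13.93.

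Plasma from before NHD was next compared with control plasma, to set uremic plasma beside it. The labels state neither the share of control plasma nor a batch. This comparison and that of after NHD with control plasma therefore also hold any difference in these. A minority of the measured genes of energy metabolism and of the contractile apparatus passed, most of them higher with uremic plasma. The fast cardiac myosin heavy chain Myh6 rose by 0.67 ± 0.14 log2 units (adjusted p = 0.025), the calcium release channel Ryr2 by 1.17 ± 0.29, the potassium channel Kcnj2 by 1.14 ± 0.25 and the myosin-binding protein Mybpc3 by 0.77 ± 0.19. These were the 4 of 26 contractile and calcium handling genes that passed (10 adjusted over the list alone), and none fell. In mitochondrial respiration and the TCA cycle, 4 of 37 genes rose, Dlat by 1.34 ± 0.25, Uqcrc2 by 0.99 ± 0.22, Ndufs1 by 0.57 ± 0.16 and Cs by 0.49 ± 0.12. Fads2 (0.99 ± 0.17), Fasn (0.73 ± 0.14) and Acaca (0.50 ± 0.11), all of fatty acid synthesis, rose among 16 lipogenesis genes. Slc16a3, a lactate exporter, rose by 1.46 ± 0.29 and Hk1 by 0.51 ± 0.14 among 31 genes of glycolysis, and Ppargc1b by 0.91 ± 0.16 among 31 of fatty acid oxidation. Dnajb9 (-0.91 ± 0.24) and Dnajc3 (-0.39 ± 0.11), chaperones of the endoplasmic reticulum, fell among 27 ER stress genes. Camera called these 6 lists (adjusted p from 5.5e-07 to 0.047), but none was called with an estimated correlation (adjusted p = 0.99 for each) and fry called 0. The ER stress call was also lost with the replicate number as a block (adjusted p = 0.18), without the samples numbered 4 (0.079), without before replicates 1, 2, 4 and 6 (0.12, 0.050, 0.12 and 0.083), control replicate 2 (0.22) or either phenylephrine array (0.051). The lipogenesis call was lost with the SD of each array as a term (0.061).

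The largest single increases were in mrpl11, a protein of the mitochondrial ribosome (2.43 ± 0.52), Ptdss2 (2.21 ± 0.53), the DNA damage checkpoint gene Hus1 (2.19 ± 0.47), Zup1, Clcc1, Mpi, Corin, Ptges2, Pigq and Nme6, the last at 1.85 ± 0.34. Corin is the protease that processes the precursor of atrial natriuretic peptide, and rose by 1.96 ± 0.55. The largest decreases were in a histone gene, H2ac25 (-2.22 ± 0.34), and in Rab39a, Zfp458, Vom1r73, Ddias, Vom1r79, Reg3g, Zp2, Zfp534l1 and Zfp189, from -2.16 to -1.63. Histone, zinc finger and vomeronasal receptor genes belong to large families of similar sequence, so that their probes may be shared. Other list members that passed included Ctnnb1 (0.84 ± 0.17), Lrp6 and Sfrp1 of Wnt signalling, the endothelial marker Kdr (1.79 ± 0.49), Lamc1 and Taldo1, which rose, and Apaf1 (-1.10 ± 0.25), Gadd45b and Fst (-1.59 ± 0.44), which fell. Of the 42 cell cycle genes, Cdc25b rose (1.14 ± 0.27) and Mcm7 fell (-0.66 ± 0.17).

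In this comparison 1439 probe sets passed (840 higher, 599 lower), and at gene level 847 of 14506 (544 higher, 303 lower). Leaving out control replicate 1 or 3 left 0 calls with limma (4470 and 4762 at an unadjusted p under 0.05), as did a fit of the 9 arrays alone (4831). Without before replicate 5 there were 5101, of which more were lower (2830) than higher (2271), without before replicates 2, 6, 1 and 4 in turn 255, 426, 675 and 816, without after replicates 1, 3, 5 and 6 in turn 915, 887, 745 and 878, and without either phenylephrine array 845. With the SD of each array as a term, a setting chosen after the data were seen, 2 passed.

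Plasma from after NHD was then compared with the same 3 control arrays, to ask what difference from control plasma was left. Counted in probe sets, the difference was larger, not smaller: 8238 passed, 3754 higher and 4484 lower, which is 28.2% of those tested. Of the 840 probe sets higher with before NHD plasma, 823 were also higher here (107.9 expected for independent lists), and of the 599 lower, 562 were also lower (91.9 expected). Both comparisons share the 3 control arrays, and part of the excess may come from them. Simulated unchanged groups of the same layout, with controls simulated as well, shared 0 calls, which sets no bound, since such groups have almost no calls. The fold changes of both comparisons correlated at 0.91 across 14506 genes with a covariance of 0.21, against 0.40 and 0.011 for simulated unchanged groups. Without control replicate 1 the count was 4547 and without control replicate 3 it was 5045, and with the SD of each array as a term it was 3015.

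Of the 42 cell cycle genes, 26 rose and 2 fell (median 0.79; adjusted over the list alone, 27 rose and 3 fell), among them Top2a (4.40 ± 0.59), Kif20a (3.87 ± 0.52), Rrm2 (3.25 ± 0.46) and Ccnb2 (2.92 ± 0.40). In mitochondrial respiration 20 of 37 genes rose and 0 fell, among them Dlat (1.99 ± 0.25) and Uqcrc2 (1.55 ± 0.22), and in fatty acid oxidation 14 of 31 rose and 0 fell, among them Ucp2 (1.89 ± 0.38), Decr1 (1.80 ± 0.44) and Acadvl (1.29 ± 0.29). Glycolysis and hypoxia genes had 14 of 31 higher and 0 lower, with Slc16a3 at 2.51 ± 0.29, Pfkl at 1.95 ± 0.37 and Pfkm at 1.81 ± 0.37. Of 26 contractile genes, 13 rose and 1 fell, with Ryr2 at 1.60 ± 0.29, Mybpc3 at 1.17 ± 0.19, Tnnc1 at 0.94 ± 0.18, Myh6 at 0.84 ± 0.14 and the calcium pump Atp2a2 at 0.56 ± 0.16. Of 16 lipogenesis genes, 6 rose and 2 fell, and Fads1 (2.09 ± 0.41) and Fads2 (1.69 ± 0.17) were among those that rose. Of 27 ER stress genes, 10 fell and 0 rose, among them Dnajb9 (-1.58 ± 0.24) and Trib3 (-1.12 ± 0.25). These 7 lists were called by camera (adjusted p from 2.3e-08 to 0.020) and not with an estimated correlation (adjusted p = 0.63 for each). Camera did not call the oxidative stress list after NHD (adjusted p = 0.95) or before NHD (0.24), each against control plasma. With the replicate number as a block and without the samples numbered 4, it was called upward before NHD (0.00089 and 0.0024). In these settings it was not called after NHD (0.72 and 0.99).

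Among genes of apoptosis and p53, 13 of 32 fell and 5 rose (median -0.28; camera adjusted p = 0.15, not called). Those that fell included Bax (-2.04 ± 0.32), Apaf1 (-1.90 ± 0.25), the p53 antagonist Mdm2 (-1.81 ± 0.29) and Cdkn1a (-1.72 ± 0.22). In the NF-kB list, 8 of 33 fell and 2 rose, with Nfkb2 at -2.47 ± 0.44, Nfkbia at -2.40 ± 0.43 and Birc3 at -1.59 ± 0.27 (camera adjusted p = 0.91). The largest decreases were in Scg2, a protein of secretory granules (-5.08 ± 0.82), Vom1r73, Mok, Gdf15, a stress-induced cytokine (-3.62 ± 0.61), Cga, Pask, the drug exporter Abcb1b, Ddias, Vom1r79 and Zfp458 (-3.17 ± 0.40). Mipep, Mmachc, Ptdss2, Lynx1, Hus1, mrpl11 and Tbc1d19 rose by 3.67 to 3.25 log2 units and completed the 10 largest increases. In the hypertrophy list Myh7 (0.35 ± 0.09) and Gata4 (1.46 ± 0.30) rose and Acta1, skeletal actin, fell (-0.79 ± 0.23), while Nppa (0.05 ± 0.07) and Nppb (0.12 ± 0.23) did not pass. Cholesterol synthesis genes had 6 of 20 higher and 0 lower, Wnt signalling 7 of 24 higher and 1 lower, and heat shock 4 of 14 higher and 1 lower. Of all 14506 genes, 4788 passed in this comparison (2428 higher, 2360 lower). Counting both directions, these lists and the NF-kB list lay near that share. Markers of fibroblasts had 2 of 21 higher, endothelium 1 of 17 higher and smooth muscle 1 of 13 in each direction. Those of leukocytes had 1 of 25 lower, neural cells 1 of 10 lower and erythroid cells 1 of 7 in each direction. None of these lists was called in the main fit. Without the samples numbered 4, camera called the fibroblast, cholesterol and Wnt lists (adjusted p = 0.049, 0.016 and 0.038). With the replicate number as a block it called the last 2 (0.018 and 0.021). With the SD of each array as a term it called the apoptosis and p53 list (0.038) and the interferon list (0.022).

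**Figure D3:**
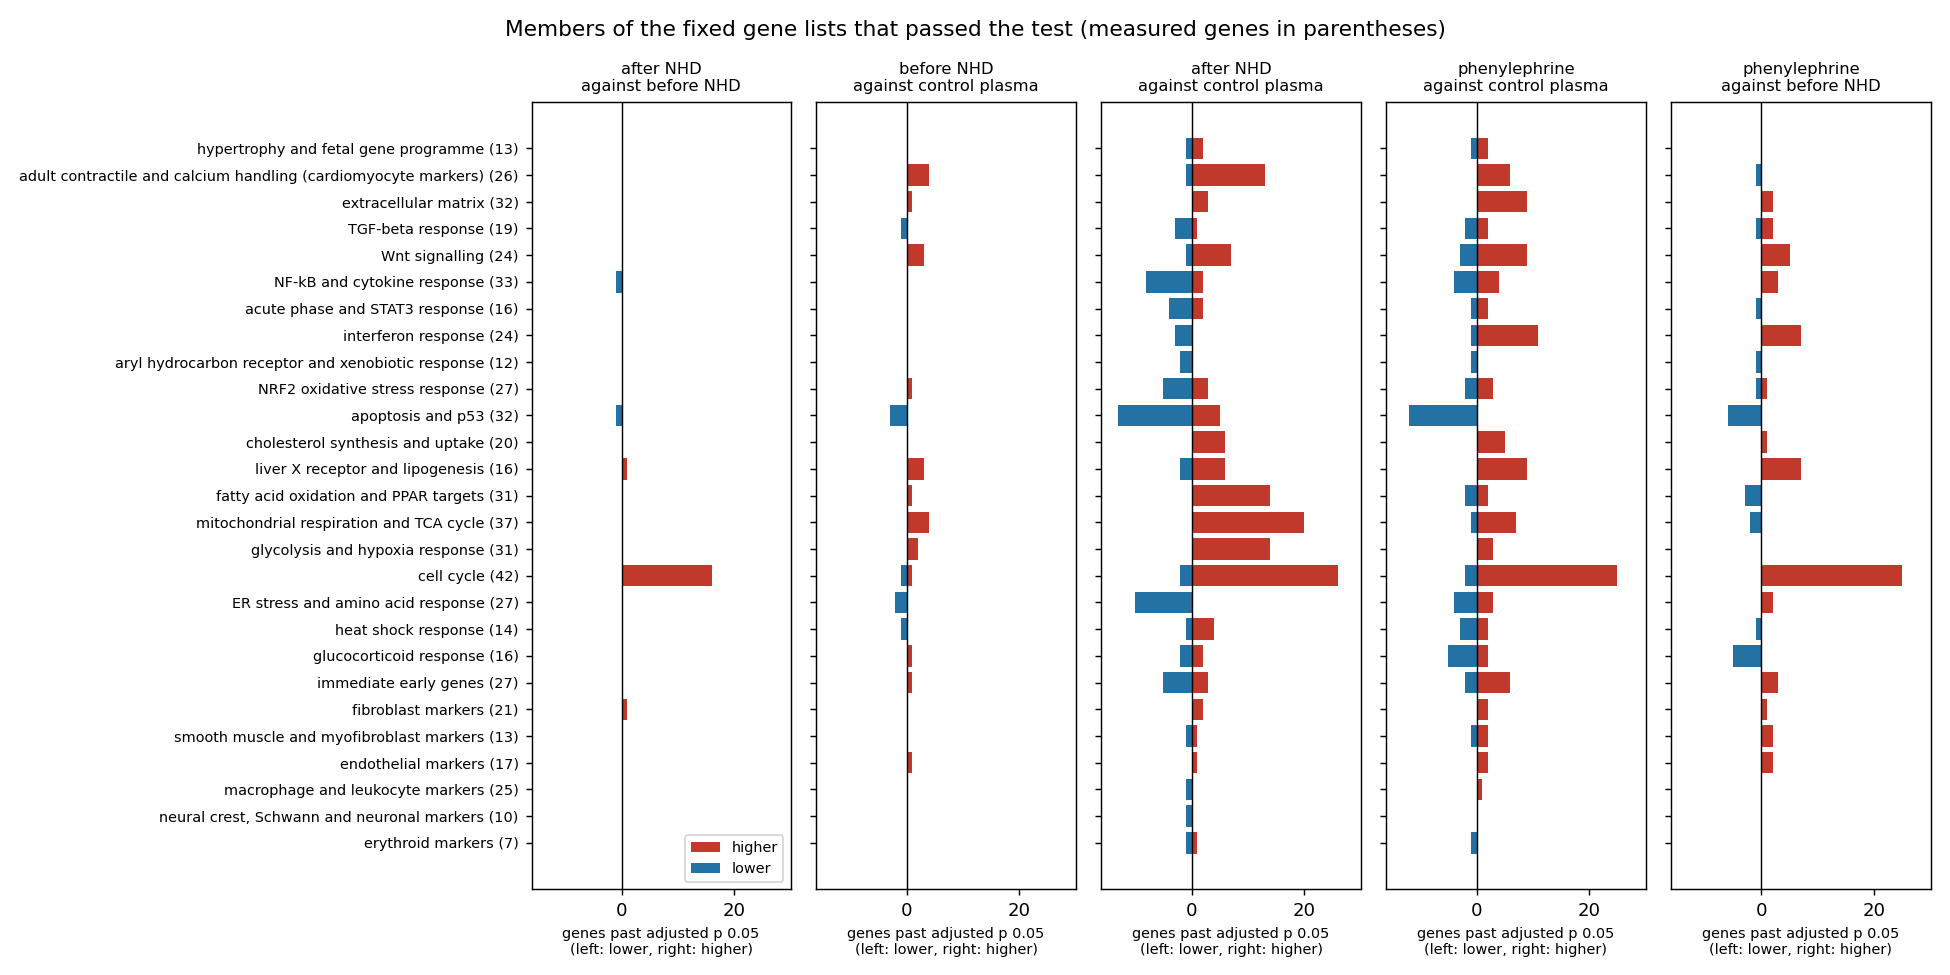
Number of genes of each fixed list that passed the adjusted p threshold in each of the 5 comparisons, higher to the right of 0 and lower to the left, with the number of measured genes in parentheses. Cell cycle genes are the longest bar in 4 comparisons (16, 26, 25 and 25 higher). Few of them pass between before NHD and control plasma (1 higher, 1 lower), a count that does not give the size of their changes.

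Whether the before NHD difference from control shrank after NHD was measured as the slope, across 14506 genes, of after minus before on before minus control. A return to the control level would give a slope below 0. With the 6 before NHD arrays split into sets of 3 so that the axes shared no before array, the mean slope over 20 splits was 0.49 (lowest 0.098, highest 0.716), positive in all 20, and it was 0.46 without the split. All splits use the same 6 before NHD arrays, and without before replicate 5 the mean slope was 0.31. Genes are not independent replicates, and the slope is a description of these arrays. The control arrays enter only the before minus control axis, but all splits use the same 3.

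**Figure D4:**
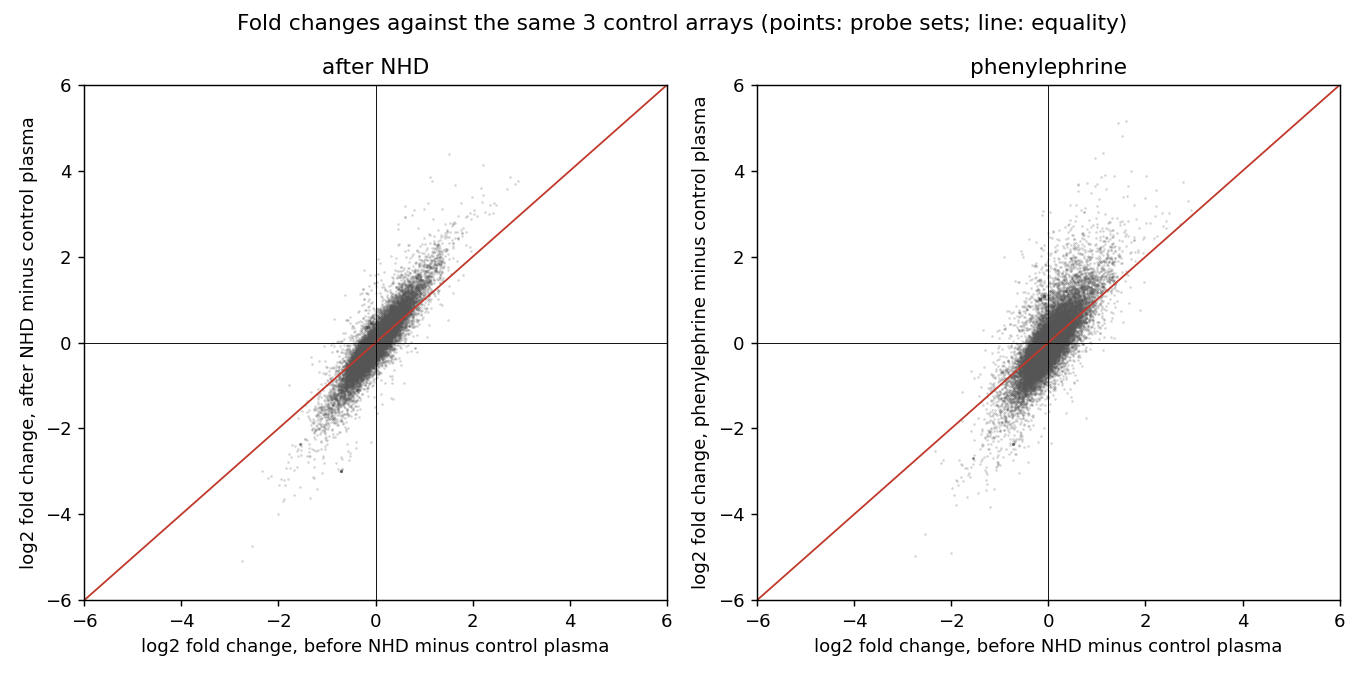
Log2 fold changes against control plasma of every probe set, before NHD on the horizontal axis and after NHD (left) or phenylephrine (right) on the vertical axis. The red line marks equal change. The left cloud runs steeper than it, with a slope of 0.46 for after minus before on before minus control across genes. All axes share the same 3 control arrays.

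Phenylephrine was compared with control plasma as the reference for a hypertrophic stimulus. The labels do not say what medium or plasma these cultures had, so that the comparison also holds any difference of medium. Of 24 interferon response genes, 11 rose with phenylephrine and 1 fell (median 1.41; adjusted over the list alone, 18 rose and 2 fell): Usp18 by 5.11 ± 1.30, Mx2 by 4.30 ± 0.94, Mx1 by 2.41 ± 0.37, Oasl by 2.27 ± 0.31 and Cxcl10 by 1.98 ± 0.42. The list mean was 8.72 and 9.13 on the phenylephrine arrays and 7.31 to 7.48 on the control arrays, but before replicate 6 reached 8.78 and after replicate 6 reached 8.08. Cell cycle genes rose in 25 of 42 cases and fell in 2 (29 and 2 adjusted over the list alone), with Top2a at 4.82 ± 0.77, Kif20a at 4.41 ± 0.68, Rrm2 at 3.85 ± 0.60 and Pbk at 3.72 ± 0.62. In lipogenesis 9 of 16 genes rose and 0 fell, with Fads1 at 3.65 ± 0.53, Fads2 at 2.91 ± 0.22 (adjusted p = 3.6e-06) and Fasn at 1.53 ± 0.18, and 5 of 20 cholesterol genes rose, among them Fdps (1.97 ± 0.42) and Sqle (1.43 ± 0.40). The hypertrophy list had 2 of 13 genes higher, Myh7 (0.53 ± 0.12) and Gata4 (1.24 ± 0.39), and 1 lower, while Nppa (0.13 ± 0.09), Nppb (0.45 ± 0.30) and Acta1 (-0.50 ± 0.30) did not pass.

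Of 32 matrix genes, 9 rose and 0 fell, among them Fbln1 (1.79 ± 0.30), Sparc (0.95 ± 0.22) and Col4a1 (0.91 ± 0.16). Beside them the fibroblast markers had a median of 1.23, with 2 of 21 passing, while Postn (3.03 ± 1.13) and Col1a1 (2.41 ± 0.89) did not pass (adjusted p = 0.072 and 0.068). In Wnt signalling 9 of 24 rose and 3 fell, with Fzd2 and Ccn4 each at 1.59 log2 units. Glucocorticoid response genes went both ways, with 5 of 16 down, among them Zbtb16 (-2.34 ± 0.28), the clock gene Per1 (-2.17 ± 0.29) and Fkbp5 (-0.95 ± 0.22), and 2 up, among them the metallothionein Mt2A (2.68 ± 0.63). Of 32 apoptosis and p53 genes, 12 fell and 0 rose, among them Cdkn1a (-1.97 ± 0.29) and Ccng1 (-1.10 ± 0.16). Mipep and Mt1 were also among the 10 largest increases, and Scg2 (-4.97 ± 1.06), Vom1r73, Cga, Zfp458, Ptprq, Abcb1b, Mok, Ddias, RT1-CE5 and Vom1r79 were the largest decreases. Camera called 9 lists, all upward: cell cycle, interferon, matrix, lipogenesis, fibroblast, Wnt signalling, glycolysis, contractile and cholesterol genes (adjusted p from 8.6e-12 to 0.028). With an estimated correlation none was called (adjusted p = 0.30 for lipogenesis, 0.62 for cell cycle and Wnt signalling, 0.78 for the others). On the brighter probe sets the calls of contractile, glycolysis, cholesterol and Wnt signalling genes were lost (adjusted p = 0.13, 0.13, 0.13 and 0.080), and without phenylephrine replicate 2 those of the first 3 (0.11, 0.41 and 0.26). The glycolysis call was also lost with the SD of each array as a term (0.052). In all 5471 probe sets passed, 2496 higher and 2975 lower, and at gene level 3427 of 14506 (1694 higher, 1733 lower). Without phenylephrine replicate 1 or 2 the counts were 1621 and 1810, and without control replicate 1 or 3 they were 3316 and 3514.

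Against before NHD plasma, phenylephrine differed in 1268 probe sets (579 higher, 689 lower). Of 42 cell cycle genes, 25 rose and 0 fell, with Top2a at 3.31 ± 0.69, Kif20a at 3.29 ± 0.60 and Ccnb2 at 3.07 ± 0.46. Interferon genes rose in 7 of 24 cases, with Mx2 at 3.33 ± 0.84, Cxcl10 at 2.89 ± 0.38 and Oasl at 2.37 ± 0.28, and lipogenesis genes in 7 of 16, with Fads1 at 2.68 ± 0.48 and Scd at 2.55 ± 0.36. The fibroblast list had a median of 1.29 (1 of 21 rose, 0 fell) and the matrix list 1.13 (2 of 32 rose, 0 fell). The endothelial list had a median of 0.25 (2 of 17 rose, 0 fell). Of all 14506 genes 837 passed, so that the fibroblast and matrix counts lay near the share over all genes. Camera called these lists upward (adjusted p = 8.8e-07, 7.3e-10 and 0.00072). With an estimated correlation none was called (adjusted p = 0.48, 0.46 and 0.40). Zbtb16 fell by 2.39 ± 0.25, Per1 by 2.02 ± 0.26, Pdk4 by 1.73 ± 0.35 and Fkbp5 by 1.22 ± 0.20, which made 5 of 16 glucocorticoid response genes lower and 0 higher. Prrg2, Tlcd3b, Fitm2, Cdkn1c and Neto2 were also among the largest decreases, Neto2 at -1.79, and RT1-CE5 fell by 1.91 ± 0.51. Nppa (0.15 ± 0.08), Nppb (0.62 ± 0.27) and Myh7 (0.25 ± 0.11) did not pass. A list test was not fixed beforehand for this comparison. With an estimated correlation, adjusted p was 0.19 for the cell cycle list, 0.17 for lipogenesis and 0.40 for the interferon and glucocorticoid lists. The count fell to 71 (56 higher, 15 lower) and 129 (72 and 57) without phenylephrine replicate 1 or 2 and to 34 (28 and 6) in a fit of the 8 arrays alone, each with more higher than lower. It was 1934 and 2377 without before replicate 4 or 6.

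The fold changes of phenylephrine and of before NHD plasma, both against control plasma, had a Pearson correlation of 0.78 and a covariance of 0.20 across 14506 genes. Simulated unchanged groups sharing simulated control arrays, with genes drawn independently, gave a correlation of 0.38 and a covariance of 0.011. Of the covariance, 0.19 was left after the simulated part. What the 3 real control arrays have in common across genes is not in the simulation and was not removed. Of the probe sets called higher before NHD, 625 were also higher with phenylephrine (71.8 expected for independent lists), and of those called lower, 448 were also lower (61.0 expected). The 3 control arrays cannot be divided into sets of 2, and part of the excess may come from them.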

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

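The tests of the wider before NHD spread, of the arrays' dynamic range and of batch for the distance from control plasma, and that of fibroblasts for the interferon genes, were chosen only after the result was seen. Single samples far from the rest of their group were looked for in 116 values, of which 11 had one, against 5.8 expected by chance. After replicate 4 accounted for 9 of them. Its cell cycle list mean was 8.9997 (others 9.44 to 9.67), with Top2a at 9.77 (10.33 to 10.57), Kif20a at 8.88 (9.77 to 10.29), Ccna2 at 9.69 (10.30 to 10.41), Rrm2 at 9.81 (11.01 to 11.60), Ccnb1 at 9.53 (10.52 to 10.86) and Nusap1 at 9.13 (9.69 to 9.89). It lay at 15.15 on the first principal component (others 32.39 to 37.20), and the interquartile range of its deviations from the probe set medians was 0.291 (others 0.224 to 0.243). Before replicate 4 had the highest hypertrophy list mean, 13.10 (others 12.33 to 12.56), and the highest Myh7, 13.20 (12.82 to 12.96). These values are not independent of each other, since most are cell cycle genes of 1 array.

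After NHD plasma lay further from control plasma than before NHD plasma did. A wider spread of the before NHD arrays alone stays open: the mean slope was 0.491 over 20 splits (0.306 without before replicate 5), but all splits use the same 6 arrays, whose mean could lie nearer the controls by chance. The arrays' dynamic range stays open too, since control replicates 1 and 3 had among the narrowest: with each array's SD as a term, 2961 of the 8238 probe sets stayed called, and this term is itself tied to the groups. A culture or array batch could not be tested, because the first component held 45.7% of the variance and no batch label can be set against it. An effect of the plasma after NHD remains untested against these.

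Cell cycle genes were higher after NHD than before. The arrays' dynamic range alone is argued against, since the list's median was 0.872 with the array SD as a term and 0.881 without. A larger share of dividing fibroblasts stays open: the list rose by 0.68 log2 units more than the fibroblast list, which could be chance (exact two-sided permutation p = 0.214, n = 6 and 6). The fibroblast list mean was 0.38 higher (exact permutation p = 0.48). A change in the myocytes themselves was not tested.

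Interferon genes differed widely between samples of 1 group, with list means of 7.01 to 8.78 before and 7.04 to 8.08 after NHD. The list's SD between samples (0.654 before, 0.411 after) lay at percentile 100 of 10000 random lists of matched level in both groups. Interferon genes thus varied together more than genes drawn at random. Quantile normalization reduces spread shared by all genes, and any list of genes regulated together would exceed random ones. The comparison therefore decides little about shared spread. A share of fibroblasts stays open, and so do other cell types: the Pearson correlation with the fibroblast list was 0.879 before (exact permutation p = 0.0222; rho 0.543, exact p = 0.297) and 0.858 after NHD (exact p = 0.05; rho 0.943, exact p = 0.0167), with adjusted p = 0.1 for both r over 6 tests. Without the 2 samples farthest from the median r was 0.019 before, where the relation rests on those samples, and 0.83 after NHD. With the macrophage and leukocyte list r was 0.694 before (exact permutation p = 0.132, adjusted p = 0.198; without 2 samples 0.964) and 0.913 after NHD (exact p = 0.0347, adjusted p = 0.1; without 2 samples 0.747), and rho was 0.886 in both groups (exact p = 0.0333 in each).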

How the results depend on the processing

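The settings without the before and after samples numbered 4 and with the array SD as a term were chosen after seeing the data. The others were fixed earlier. Of the values of named genes that passed, taken over all settings, those that kept and lost the call numbered 307 and 291 for after against before NHD, 782 and 435 for before NHD against control plasma, 1825 and 43 for after NHD against control plasma, 1711 and 75 for phenylephrine against control plasma, and 857 and 127 for phenylephrine against before NHD. Values that had not passed and passed under a setting numbered 106, 35, 4, 16 and 35 in the same order. No named gene that passed changed direction. A second quantile normalization and a trended robust prior left every count of probe sets within 1.5 times. The cause of the differences below was not tested, except where fewer probe sets were tested or a minimum fold was added.

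For after against before NHD (116), the brighter probe sets gave 393, a fit of only these groups 0 (4614 at an unadjusted p under 0.05 with limma), array weights 3186, leaving out the samples numbered 4 2677 (1115 higher, 1562 lower, where the balance turned), and the array SD term 65. For before NHD against control plasma (1439), only these groups gave 0 (4831 unadjusted), array weights 6929 and the array SD term 2. For after NHD against control plasma (8238), 1 probe set per gene gave 5005, array weights 14916, a 1.5-fold minimum 5051 and the array SD term 3015. For phenylephrine against control plasma (5471), only these groups gave 9072 and array weights 12602. For phenylephrine against before NHD (1268), only these groups gave 34, array weights 4764, leaving out the samples numbered 4 2399 and the array SD term 2022.

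With the replicate number as a block, the counts were 316 for after against before NHD (134 higher, 182 lower, where the balance turned), 3329 for before NHD against control plasma and 2447 for phenylephrine against before NHD, and the other counts stayed within 1.5 times. Deviations of same-numbered before and after samples correlated at -0.025 to 0.599 over 6 pairs, and 6 of these 12 samples correlated best with their own number, those numbered 2, 3 and 4 (0.422, 0.599 and 0.571). Not every pair lay above 0.1, so that the block was kept as an alternative, and whether the numbers pair the samples stays open.

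Camera called 8, 6, 7 and 9 lists in the first 4 comparisons. With an estimated correlation it called 0, 0, 0 and 0, and fry called 2, 0, 11 and 5. The brighter probe sets gave 5 for phenylephrine against control plasma.

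Leaving out each sample in turn gave 0 to 2690 probe sets for after against before NHD, 0 to 5101 for before NHD against control plasma, 4547 to 8862 for after NHD against control plasma, 1621 to 6330 for phenylephrine against control plasma and 71 to 2377 for phenylephrine against before NHD. The lowest and highest are those without before replicate 1 (and 7 others) and before replicate 6, control replicate 1 (and control replicate 3) and before replicate 5, control replicate 1 and before replicate 5, phenylephrine replicate 1 and before replicate 5, and phenylephrine replicate 1 and before replicate 6. Lists called were 5 (without before replicate 3) to 11, 5 to 7, 7 to 10 and 7 to 10. The correlation of fold changes was 0.762 to 0.799 and the slope 0.306 (without before replicate 5) to 0.534. A lone phenylephrine array was assumed to vary like the other groups. Dim probe sets limit what the arrays show, since their differences are compressed.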

Other observations

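The comparison of phenylephrine with after NHD plasma, the gene families and the p53 list below were chosen only after the results were seen. Against after NHD plasma, phenylephrine differed in 286 probe sets (141 higher, 145 lower). Cxcl10 rose by 3.11 ± 0.38 log2 units (SE, n = 2 and 6; limma adjusted p = 0.00070), Oasl by 2.32 ± 0.28, Mx1 by 2.12 ± 0.33 and Ifit3 by 2.05 ± 0.29. Zbtb16 fell by 1.68 ± 0.25, Per1 by 1.59 ± 0.26 and Fkbp5, a chaperone of the glucocorticoid receptor, by 1.36 ± 0.20. All 7 genes were picked after their values were seen, and the last 3 also fell against control and before NHD plasma. Neither the interferon nor the glucocorticoid list was tested in this comparison. The interferon list mean ranged from 7.04 to 8.08 within the after NHD group, and against control plasma the glucocorticoid list went both ways (5 fell, 2 rose; camera adjusted p = 0.37). Whether the phenylephrine cultures had plasma is not stated.

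Genes of mitochondrial ribosomal proteins, 71 in number, had no list test here. With after NHD against control plasma, 39 rose, 7 fell and 25 did not pass, where 4788 of all 14506 genes passed. The counts were 38 and 7 after a second quantile normalization, and 19 and 6 with the array SD as a term. With before NHD against control plasma, where 847 of all 14506 genes passed, 16 rose and 0 fell. The second normalization gave 15 and 0, and the array SD as a term in limma 0 and 0. With phenylephrine against control plasma 16 rose and 14 fell (median 0.03). Between after and before NHD, 0 rose and 0 fell. Canonical histone genes had 7 of 14 lower and 2 higher with after NHD than with control plasma (7 and 2 after the second normalization, 4 and 2 with the array SD as a term), and near-identical copies may share probes there. Of 1105 olfactory receptor genes, with a median level of 4.98, 226 were lower in that comparison, 128 after the second normalization (2 higher) and 13 with the array SD as a term. The median log2 difference was -0.12 in the dimmest of 4 equal parts of the probe sets and 0.01 in the brightest.

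A hypothesis is that the p53 programme as a whole was lower after NHD than before, as Cdkn1a was. A list of p53 target genes had 24 measured members, of which 2 fell and 20 were lower (median -0.51; camera with an estimated correlation, p = 0.0180). Of them, 10 had not been noticed before and were in no fixed list. The p over all 24 includes genes noticed in these data and lends no support of its own. Of the 10, 8 were lower and 0 passed, with a median of -0.31 (camera with an estimated correlation, p = 0.0132). That is the direction the hypothesis predicts, but the list was written on these data and these p-values are not adjusted. The 10 genes were read on the same arrays that raised the hypothesis, so that their p lends it no independent support. The apoptosis and p53 list fixed beforehand was not called with an estimated correlation (adjusted p = 0.71). Nor did its mean separate the groups (exact permutation, adjusted p = 0.15 over 27 lists). For the 24 genes, p with an estimated correlation was 0.139 for before NHD against control plasma (median -0.54), 0.0462 for after NHD against control plasma (median -1.07, 17 fell, 1 rose) and 0.0577 for phenylephrine against control plasma (median -1.15, 17 fell). For the 10 genes, p by the same test was 0.212, 0.0472 and 0.0601 in the same order.

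Other splits of the same samples into groups of the same sizes were run to see whether chance can be excluded. For after against before NHD, 4 of 100 drawn splits (462 possible), the real one included, gave as many probe sets as the real 116. That share lies under 0.05, but too near it for a draw of this size to exclude chance firmly. The highest other count was 1025, for the split that exchanged before replicate 4 and after replicate 2, several times the real count, which points to a structure of the samples. For before NHD against control plasma, chance was not excluded: 6 of 84 splits gave 1439 or more, the highest other 5023, which joined before replicate 5 to control replicates 1 and 3 and again points to structure. For after NHD against control plasma, 1 of 84 splits, the real one, gave 8238, with 1 as the highest other. That is the lowest share that 84 splits can give, and it argues against a chance division of these arrays. A culture or array batch shared by the control arrays could give the same result. For lists called by camera, chance was not excluded. As many lists as the real 8, 6 and 7 came from 69 of 100, 72 of 84 and 63 of 84 splits. The highest others were 18, 19 and 16.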
